A study of Danio rerio with 2 samples.

How the data were processed

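The files deposited by the authors hold UMI counts per gene and barcode for 2 libraries of sorted eGFP-positive retinal cells, 1 per injury, and the values were whole numbers with no barcode under 500 UMIs. Per the labels' protocols the cells were captured on the Chromium platform and sequenced on a NovaSeq instrument. The submitters' processing notes name Cell Ranger and Scanpy and the builds GRCz11 and danRer11, with no versions and no roles, and the settings of alignment and barcode calling are not given in the sources used here. The counts were used as deposited. Reads of near-identical gene copies can be split or lost by the authors' counting, which matters most for the tandem green and red opsin genes, so these were summed per opsin group. No reference genome was used, and gene names came from the files, which list 25432 genes, of which 1167 share a symbol with another.

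Groups were taken from the sample labels, light damage and NMDA, with 1 library each. The design was fixed before the data were examined, with 18 marker lists, 31 gene lists, the rule for the genes named and the alternatives. Barcodes were kept from 500 detected genes and up to 25% of UMIs from the 13 mitochondrially encoded genes. In the light damage library 3929 barcodes fell under 500 genes, 195 of the others passed the mitochondrial limit and 408 more were predicted doublets. In the NMDA library these numbers were 2898, 87 and 713. Doublets were predicted per library with Scrublet at an expected rate of 0.08. Its automatic threshold marked no barcode in the NMDA library, so a score of 0.25, chosen after this was seen, was used in both and marked 3.17% and 3.97% of the scored barcodes.

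Kept cells of both libraries were log-normalized and clustered together in Scanpy 1.11.5, with 2000 variable genes, 40 principal components, 20 neighbours and the Leiden method at resolution 1. A cluster took the name of a class when at least 3 of the class's fixed markers were enriched in it by 2-fold in at least 10% of its cells and at least 2 stood among its 50 leading genes. It stayed unnamed when another class had at least 0.5 times as large a share of its markers enriched, or more markers among the 10 leading genes, with cycling and neurogenic precursor markers allowed together. It also stayed unnamed when its cells of each library had a median UMI count under that library's median divided by 3, with no own marker among its 10 leading genes. The same held when it had Müller glia markers with presynaptic genes at 0.5 times their mean over clusters or more. Only the markers were fixed beforehand. This naming rule was set and revised after the clusters were seen, and so was the rule that a sub-cluster share is given only where all 10 leading genes stood within 2-fold between libraries and each library had at least 5% of the class in it. Names ending in "-like" are therefore rebuilt names. Sub-clusters came from reclustering each class at resolution 0.5.

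Classes with at least 200 cells in each library were compared. UMIs were summed per class and library and given as CPM of the class's sum, with exact Poisson intervals, and ratios have exact conditional intervals. Shares have exact (Clopper-Pearson) binomial intervals. All are 95% intervals of counting error, and none covers the spread between animals, so no p-value and no count of changed genes was computed. A log2 ratio has 1 CPM added to both sides. A share or level of 0 was given a floor of 3 counts, which allows shares of up to 0.0236% and 0.0173% of kept cells. For a gene list, the median log2 ratio of its members with at least 10 CPM in the mean of both libraries was ranked among 10000 random lists of the same size matched on expression. Lists with under 3 such members were left out. This gave 189 medians over lists and classes, of which 40 lay above and 43 below the central 95% of random lists. The lists that lead the text, and the 8 plotted, were picked after all of these had been seen.

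Genes named singly had at least 50 CPM in the higher library and there at least 0.5 times the level over all cells of that library. Of these, the 3 with the largest log2 ratio in each direction were taken per class, without clone and locus names. From a list the text speaks of, the 2 members with the highest and the 2 with the lowest ratio could be named. The list of lineage and sort genes had only mmp9 among the files' genes and gave no median.

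Alternatives covered the limits on genes, mitochondrial share and doublets, the Leiden resolution, clustering of each library alone, a class per cell from its marker share, thinning to 1000 UMIs, scaling, the minimum level of list members and the opsin call. In the thinned sets 183 and 374 cells under 1000 UMIs were left out. For the class per cell, 2316 light damage and 2980 NMDA cells had a second class within 20% of the first. Naming every cluster with at least 3 enriched markers by its best class was added after the data were seen. So were taking the largest cluster of a class alone and, for class shares, keeping cells from 200 detected genes. Clusters with under 3 enriched markers stayed unnamed throughout. The barcodes under 500 genes had no doublet score. The intervals were tested on simulated Poisson counts drawn from the real means, with 200 genes changed. Such counts meet what the intervals assume. The test therefore checks the computation, and not genes whose UMIs lie in few cells. In Müller glia-like sums 94.9% of the intervals of doubled genes held the true ratio over 100 draws, with a range of 88 to 99% between draws, and in amacrine-like sums 96.2% (92 to 100). The number of draws had been raised after a first low value. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9 were used.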

Results

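The data were 2 single-cell RNA libraries of adult zebrafish retina, 1 from eyes lesioned with intense light and 1 from eyes injected with NMDA, a glutamate receptor agonist that kills inner retinal neurons. Intense light kills mainly photoreceptors. Müller glia of the fish retina answer both injuries by dividing and giving rise to new neurons. In the line used, the promoter of mmp9, a matrix metalloproteinase gene, drives a tamoxifen-dependent recombinase that switches a dsRed reporter to eGFP, and cells positive for eGFP were sorted before capture. The sample titles give 15 days after injury and the series design gives 14 days. The comparison asks which classes the sorted cells fell into, and in what state they were, after each kind of injury.

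The light damage library held 17256 barcodes with 109934212 UMIs and the NMDA library 21054 barcodes with 115947536 UMIs. After filtering, 12724 and 17356 cells remained, with medians of 6580 and 5027 UMIs and of 2254 and 1884 detected genes per cell. Barcodes with over 50% mitochondrial UMIs made up 13.3% of the light damage library and 5.34% of the NMDA library. Each injury had 1 library, so no difference below has a replicate check. Intervals in parentheses are 95% intervals of counting error alone. The number of animals behind each library is not given in the sources used here. The genes counted did not include eGFP, dsRed or the recombinase under any of the names searched. Cells that passed the sort without the reporter could therefore not be told from labelled ones. A neuron-like cell is thus not shown to be progeny of the glia. Over all kept cells mmp9 stood at 2.30 CPM (counts scaled to the total UMIs of the cells) in the light damage library and at 10.1 in the NMDA library, and in Müller glia-like cells at 1.54 and 15.9.

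Both libraries held Müller glia-like cells, cycling cells and cells of each of the 6 neuron-like classes. Named by clusters, Müller glia-like cells were the largest class, at 43.5% of light damage cells (42.7 to 44.4) and 36.0% of NMDA cells (35.3 to 36.7). With a class given to each cell by its own markers, Müller glia-like cells took 11.1% and 6.59% against 11.3% and 9.97% for rod-like cells. By that count cycling, amacrine- and ganglion-like cells, at 6.72%, 8.10% and 6.70%, also exceeded Müller glia-like cells after NMDA. That count divides each marker score by its mean over all cells, which lowers the scores of a common class. Cells could also go to marker lists outside the classes compared, so the shares of these classes do not add up to all cells. The count per cell therefore cannot decide which class was largest. Inner retinal classes took larger shares after NMDA. Amacrine-like cells, the inhibitory interneurons of the inner retina, made up 1.81% (1.58 to 2.05; 230 cells) after light damage and 5.16% (4.84 to 5.50; 896 cells) after NMDA, a ratio of 2.86 (2.47 to 3.32). Ganglion-like cells, the output neurons, made up 1.57% (1.36 to 1.80) and 3.11% (2.85 to 3.37), a ratio of 1.98 (1.68 to 2.34). Bipolar-like cells made up 3.64% and 5.38%, a ratio of 1.48 (1.32 to 1.66), and horizontal-like cells 4.72% and 5.58%, a ratio of 1.18 (1.07 to 1.31).

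Photoreceptor-like and cycling cells did not share that direction. Rod-like cells made up 8.66% of the light damage library and 7.14% of the NMDA library, a ratio of 0.824 (0.759 to 0.895). Cone-like cells made up 3.25% and 3.09%, and the interval of their ratio, 0.835 to 1.08, included no difference. That did not hold under other mitochondrial limits, where cone-like cells made up 2.32% and 1.77% (at most 10%, log2 ratio -0.39) or 4.08% and 3.35% (no limit, -0.28). Cycling cells, marked by replication and mitosis genes such as pcna and mki67, made up 13.1% and 10.2%, a ratio of 0.775 (0.725 to 0.829). These shares were of sorted eGFP-positive cells, and the libraries differed in depth. When each library was clustered alone, the log2 ratio of shares of Müller glia-like cells went from -0.28 to 0.13 and that of cycling cells from -0.37 to 0.0196, and those of amacrine-, horizontal- and rod-like cells became 2.44, 1.02 and -1.45. The rod-like shares were then 19.2% and 7.01%, so the light damage share rose while the NMDA share hardly moved. Whether some clusters were named rod-like in 1 library only was not tested. With the class per cell, the log2 ratio of ganglion-like cells was 0.20 in place of 0.98.

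**Figure D1:**
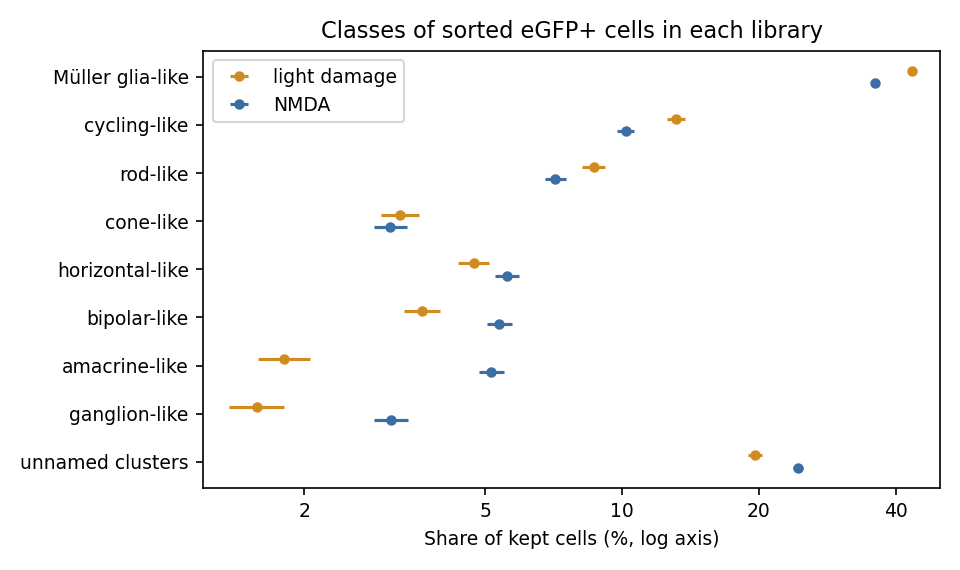
Share of kept eGFP-positive cells (%, log axis) in each named class and in the unnamed clusters, for the light damage library (orange) and the NMDA library (blue), with lines for exact 95% binomial intervals that cover counting error alone. Amacrine-like cells lie at 1.81% and 5.16%, and Müller glia-like cells at 43.5% and 36.0%.

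Of 43 clusters, 17 stayed unnamed and held 19.7% of light damage and 24.4% of NMDA cells. The largest of them, cluster 1, was led by sox11b, a transcription factor of young neurons, with pnoca and prdm1b, and took 10.7% of light damage and 10.6% of NMDA cells. Its closest class was rod, with 2 enriched markers, under the 3 that a name needs. Clusters with amacrine markers that the naming rule kept out held 0.998% and 3.07% of the cells. Those with bipolar markers held 1.92% and 2.09%, those with Müller glia markers 4.13% and 5.04%, and 1 with rod markers 0.259% and 0.161%.

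Within classes, shares of sub-clusters were compared where all 10 leading genes stood within 2-fold between the libraries and each library had at least 5% of the class. A Müller glia-like sub-cluster led by smoc1, rdh10a and aldh1a3, of which the last 2 encode enzymes that make retinoic acid, held 12.3% (11.4 to 13.2) of Müller glia-like cells after light damage and 18.0% (17.1 to 19) after NMDA. Each of the other Müller glia-like sub-clusters had a leading gene that differed by more, so their shares are not compared. Several were mostly of 1 library, such as 1 led by inhbb and serpine3 with 1110 light damage cells and 1 NMDA cell, 1 led by stc2a and smox with 1445 and 230, and 1 led by coch and unc5b with 206 and 1777. The same held for a horizontal-like sub-cluster of 210 and 10 cells and an amacrine-like one of 8 and 276. With 1 library per injury these are not read as cell types, and the values of a class are over its whole mix. A horizontal-like sub-cluster led by gad1b, which encodes a GABA-synthesizing enzyme, and slc6a1l held 32.9% (29.2 to 36.9) and 12.3% (10.3 to 14.5). Among cycling cells, a sub-cluster led by histone genes held 26.8% and 27.4%, and 1 led by pcna and mcm2, which act in DNA replication, held 21.3% and 16.8%. The mitotic sub-cluster, led by kpna2, nusap1 and ube2c, held 11.4% and 10.2%, with overlapping intervals of 9.88 to 13.0 and 8.86 to 11.7. In amacrine-like cells a sub-cluster led by enox2, pde6gb and kif26aa held 24.8% (19.3 to 30.9) and 10.9% (8.97 to 13.2). Another of amacrine-like cells, led by megf11 and ngfra, held 20% and 7.25%.

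Sub-clusters with Müller glia genes among their leading genes lay inside other classes too. A rod-like sub-cluster led by icn, mdka and rlbp1a held 16.1% (13.9 to 18.4) of rod-like cells after light damage and 24.7% (22.3 to 27.2) after NMDA. An amacrine-like sub-cluster led by her6 and ptgdsb.2, with apoeb, held 10.4% and 10.5%, and a cycling sub-cluster led by her6 and id1, with glula and rlbp1a, held 10.6% and 15.2%. Sub-clusters with apoeb, glula and cahz among the leading genes were also found in horizontal-, bipolar- and ganglion-like cells but did not meet the rule for a share. The median was 12708.5 UMIs in the amacrine-like one, against class medians of 6728 and 5039.5, and 22635 in the ganglion-like one, against 16042 and 12443. The rod-like and cycling ones lay below their class medians, at 2989 and 9592. Whether doublets or free RNA put glial genes there was not tested. The remaining sub-clusters that met it were led by tmtops2a and dlg2 in rod-like cells (12.3% and 5.49%), by mitochondrially encoded genes in cone-like cells (35.3% and 56.4%), by guca1c and neto1l in bipolar-like cells (13.0% and 15.6%), and by crhb (8.5% and 6.31%) and sox6 (9.5% and 5.38%) in ganglion-like cells. At a finer resolution the mitotic genes kpna2, nusap1 and ube2c stood among the leading genes of a pair of cycling sub-clusters, at 15.12% (13.4 to 16.9) and 11.6% (10.1 to 13.2) and at 9.21% and 7.46%, so that the intervals of the larger no longer overlapped. The histone genes led a sub-cluster of 12.3% and 15.4% of cycling cells, pcna and mcm2 stood among the leading genes of 1 of 11.4% and 8.25%, and her6 led 1 of 9.62% and 8.93%. The rod-like sub-cluster with icn, mdka and rlbp1a then held 11.6% and 16.1%, and the cone-like one of mitochondrially encoded genes 27.1% and 31.5%. Of the amacrine-like genes, enox2 and kif26aa then stood in a sub-cluster of 10% and 3.46% and pde6gb in another of 14.8% and 7.48%.

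Among cone-like cells with a most abundant opsin group, red opsin led in most cells of both libraries, and UV opsin led in a larger share after NMDA. Zebrafish have 4 cone types, each with its own opsin. Of 340 such cells after light damage and 343 after NMDA, red opsin led in 77.9% (73.2 to 82.2) and 70.8% (65.7 to 75.6). UV opsin led in 2.06% (0.832 to 4.2) and 13.1% (9.73 to 17.2), that is in 7 and 45 cells. Green opsin led in 17.4% and 12.8% and blue opsin in 2.65% and 3.21%, with overlapping intervals in both cases. By opsin UMIs, red took 86.5% and 56.4%, green 8.55% and 29.9%, UV 4.37% and 10.8%, and blue 0.591% and 2.92%. The green share thus went opposite ways by cells and by UMIs. A call from 10 opsin UMIs, with 80% in 1 group, put green at 8.55% (4.63 to 14.2) and 16.7% (10.9 to 24), in the direction of the UMIs but with overlapping intervals, and no direction is read from it.

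UMIs of UV opsin were found in 2.66% of cone-like cells after light damage and 9.68% after NMDA, at median depths of 5330 and 5162 UMIs. In Müller glia-like cells, which should lack opsins, the same shares were 0.181% and 0.449% at medians of 7498 and 6200.5 UMIs. They were highest outside the cone-like class in rod-like cells, at 1.54% and 3.23% with medians of 5084 and 4179 UMIs, where UV opsin stood at 4.09 and 23.0 CPM against 153 and 270 in cone-like cells. Thinned to 1000 UMIs per cell, UV opsin led in 2.43% and 15.2% of the 247 and 231 cells with a most abundant opsin group. With at most 10% mitochondrial UMIs the NMDA share was 22.8%. Of all cone-like cells 65.7% and 48.0% had a UMI of red opsin, and no opsin UMI was found in 72 light damage and 192 NMDA cells. Cone-like cells came from 2 clusters, of which cluster 12 held 85.0% of them after light damage and 69.1% after NMDA and cluster 26 held 15.0% and 30.9%.

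**Figure D2:**
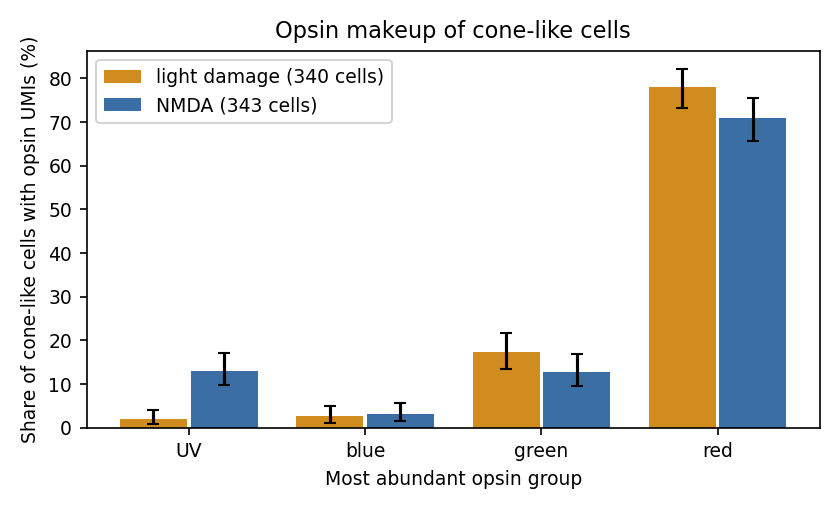
Share of cone-like cells (%) by most abundant opsin group (UV, blue, green, red) in the light damage library (orange, 340 cells) and the NMDA library (blue, 343 cells), with exact 95% binomial intervals that cover counting error alone. Red opsin leads in 77.9% and 70.8%, and UV opsin in 2.06% and 13.1%.

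Genes of the interferon response and antigen presentation were higher in the NMDA library in all 8 classes. In Müller glia-like cells each of the 17 measured genes of this list was at least 1.5-fold higher after NMDA, with a median log2 ratio of 2.23. The antiviral GTPase gene mxb stood at 5.62 and 109 CPM (log2 4.06) and stat1b, which encodes a transcription factor of interferon signalling, at 12.1 and 202 (3.95). The smallest log2 ratios in the list were 1.17 for stat1a and 0.82 for irf9, both encoding interferon signalling factors. The median was 4.18 in amacrine-like (10 genes), 3.35 in horizontal-like (11), 3.06 in cone-like (5), 1.98 in bipolar-like (8), 1.90 in ganglion-like (13) and 1.1 in rod-like cells (5), and it was 0.90 in cycling cells (8). Müller glia markers stood in amacrine-like cells at a median of 13.5% of their level in Müller glia-like cells after NMDA. In rod-like cells 4 of 5 members were higher after NMDA, with irf9 at log2 -0.02, and in the other classes every measured member was.

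The ubiquitin-like modifier gene isg15 (ENSDARG00000086374) showed how far single members went. It stood at 9.65 CPM after light damage and 784 after NMDA in horizontal-like cells, at 2.95 and 271 in bipolar-like cells, and at 1.56 and 51.9 in cone-like cells. After NMDA isg15 was found in 247 of 969 horizontal-like cells and in 83 of 933 bipolar-like cells, where 10 cells held 46.9% of its UMIs, and at the finer resolution it led a horizontal-like sub-cluster of 2 and 116 cells. In amacrine-like cells stat1b and rsad2, which encodes the antiviral enzyme viperin, had no UMI after light damage and stood at 106 and 98.4 CPM after NMDA. With the 4 such members at a floor of 3 counts, the amacrine-like median was 3.83, and with predicted doublets kept 3.45. Each of the 8 class medians of the list lay at percentile 100 of 10000 random lists of the same size and expression, which describes these libraries and is no test. Most Müller glia-like cells came from clusters 0, 2 and 7 after light damage and from 3, 0 and 4 after NMDA, and cluster 3 was itself led by interferon genes. Within cluster 0 alone the median was 0.71. With members counted from 1 UMI the medians were 2.38 in amacrine-, 1.95 in horizontal- and 1.78 in cone-like cells.

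Immediate early genes, which are induced within minutes of stimulation or stress and many of which encode transcription factors, were lower in the NMDA library in most classes. The median log2 ratio was -1.43 in bipolar-like (18 genes), -1.06 in rod-like (16), -0.60 in Müller glia-like (19), -0.55 in ganglion-like (18) and -0.33 in cycling cells (15), at percentiles of 0.715 or below. In amacrine-like cells it was -0.33 at percentile 4.69 and in cone-like cells -0.18 at percentile 9.94, while in horizontal-like cells it was 0.09 at percentile 64.7 and, within their largest cluster alone, -0.47. Within the largest cone-like cluster it was 0.0723. The stress-induced gene atf3 went from 1393 to 237 CPM in rod-like cells (log2 -2.55) and from 1046 to 296 in Müller glia-like cells (-1.82). In bipolar-like cells fosab, the fish c-Fos gene, went from 1481 to 350.0 CPM (-2.08) and btg2 from 794 to 197. Single members went the other way, such as egr1 in horizontal-like cells, at 7.06 and 27.4 CPM (1.82).

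Stress and sterol genes were lower after NMDA in several of the same classes. In Müller glia-like cells 18 of 19 cholesterol synthesis genes were lower and 13 of them by at least 1.5-fold, with a median log2 ratio of -0.86. Their largest differences were in sc5d (log2 -1.53) and hsd17b7 (-1.40), both enzymes of the pathway, and ldlra, the gene of the LDL receptor, was the exception at 0.60. The gene sc5d was among the leading genes of the Müller glia-like sub-cluster of 1110 light damage cells and 1 NMDA cell. How far that sub-cluster carried the list's difference was not tested. The list's median was -0.82 in bipolar-like, -0.65 in ganglion-like and -0.60 in amacrine-like cells. Genes of the endoplasmic reticulum stress response had a median of -0.75 in rod-like cells, where dnajb9b and hspa5, both chaperone genes, had -2.71 and -1.63. Heat shock genes had medians of -0.55 in rod-like, -0.73 in bipolar-like and -0.42 in ganglion-like cells, but 0.24 in cone-like cells. Glycolysis genes had medians of -0.78 in bipolar-like and -0.60 in horizontal-like cells, with aldoaa, an aldolase gene, at -1.38 and -1.47.

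Ribosomal protein genes were higher after NMDA in Müller glia-like cells and in most neuron-like classes. In Müller glia-like cells 42 of 43 measured members were higher, with a median log2 ratio of 0.57 (percentile 99.9). All 43 measured members were higher in cone-like cells (median log2 1.86), bipolar-like cells (0.95), amacrine-like cells (0.89) and horizontal-like cells (0.73). The median was -0.02 in ganglion-like cells, where rplp2 had 0.30 and rpl4 had -0.46. Immature neuron genes had medians of 1.88 in cone-like cells, 0.75 in bipolar-like cells and 0.33 in horizontal-like cells, and of -0.16 in ganglion-like cells. In cone-like cells stmn1a, which encodes a microtubule regulator of young neurons, went from 4.29 to 48.5 CPM and sox11a from 3.51 to 38.56. Within cone-like cluster 12 alone the median of the immature neuron genes was 0.86 and that of the ribosomal protein genes 0.79.

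**Figure D3:**
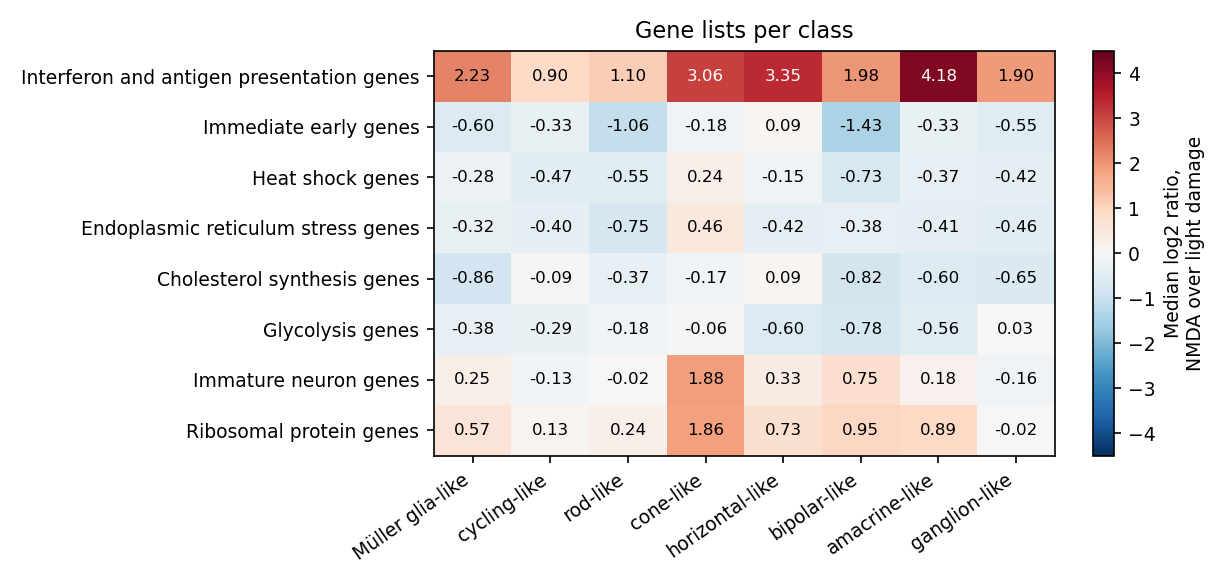
Heat map of the median log2 ratio (NMDA over light damage, printed in each cell and shown by colour, red for higher after NMDA and blue for lower) of 8 gene lists (vertical axis) in each of the 8 classes (horizontal axis). Interferon and antigen presentation genes lie above 0 in each class, from 0.90 in cycling cells to 4.18 in amacrine-like cells.

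In Müller glia-like cells ifi45, an interferon-induced gene outside the fixed list, stood at 168 and 3053 CPM, a ratio of 18.2 (17.7 to 18.6). The retinal homeobox gene rx3 was higher after light damage, at 53.5 against 6.0 CPM, a ratio of 0.112 (0.0976 to 0.128). The cell adhesion gene cdh11 stood at 73.8 and 8.89 CPM (0.121, 0.108 to 0.135) and abi3bpb at 116 and 14.4 (0.124, 0.113 to 0.135). The Notch target genes her4.1 and her4.2 had log2 ratios of -1.43 and -1.54, while the receptors notch1b and notch1a had 0.66 and 0.64, and the whole Notch and proneural list had a median of 0.10. The symbol her4.2 is shared by more than 1 gene, and the value is of the first listed. Both her4 genes led cluster 7, of 929 light damage and 195 NMDA cells. Genes of the glial injury response had a median of -0.24 (16 genes, percentile 1.46), with stat3 at 0.47 and lepb, a leptin gene, at -1.01.

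Of the genes the rule named in cycling cells, s100b, which encodes a calcium-binding protein, stood at 23.7 and 68.7 CPM (ratio 2.89, 2.63 to 3.18), adarb2 at 23.6 and 57.0 (2.41, 2.19 to 2.66) and b2m, the light chain of MHC class I, at 206 and 455 (2.21, 2.13 to 2.28). Higher after light damage were idh2, a mitochondrial isocitrate dehydrogenase gene, at 187 and 64.2 CPM (0.344, 0.323 to 0.365), flr at 53.1 and 18.0 (0.339, 0.302 to 0.38) and the transferrin receptor gene tfr1b at 56.9 and 20.3 (0.356, 0.319 to 0.397). The cell cycle list had a median of -0.22 (23 genes, percentile 6.47), with rrm2 at 0.81 and ccnb1 at -0.76. In this class the median gene of all lay at -0.12, and cell cycle genes define the class.

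Of the genes the rule named in rod-like cells, those higher after light damage were, beside atf3, ucp2, which encodes a mitochondrial carrier, at 186 and 46.5 CPM (ratio 0.249, 0.216 to 0.288) and ier2b at 91.9 and 26.1 (0.284, 0.233 to 0.345). Higher after NMDA were nat10, an RNA acetyltransferase gene, at 38.5 and 87.3 CPM (2.27, 1.92 to 2.69), tmem108 at 29.4 and 65.9 (2.24, 1.85 to 2.73) and crhr1 at 23.1 and 51.4 (2.23, 1.79 to 2.78). Rod phototransduction genes had a median of 0.10 (23 genes, percentile 81.6). Cone phototransduction genes had a median of 1.58 over 8 genes, all higher after NMDA, with gngt2b, a cone transducin subunit gene, at 16.0 and 62.2 CPM. Cone RNA, free or in doublets, was not tested as a source in rod-like cells. The median gene of all lay at -0.13 in rod-like cells.

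In cone-like cells the blue cone factor gene foxq2 had no UMI in 414 light damage cells and 67.8 CPM after NMDA, with a lower bound of 46.7 for the ratio, but from 17 cells. The green opsin gene opn1mw1 had 5.07 and 56.0 CPM, a ratio of 11.03 (6.29 to 21.1), from 4 and 14 cells, and its near-identical copies can share its reads. The photoreceptor factor gene prdm1a stood at 10.1 and 102 CPM (10.1, 6.74 to 15.6). Higher after light damage were hspg2, which encodes the matrix proteoglycan perlecan, at 363 and 8.71 CPM (0.0240, 0.0158 to 0.0349), cadpsb, a vesicle release gene, at 365 and 31.4 (0.0861, 0.0694 to 0.106), and the Wnt ligand gene wnt2bb at 146 and 18.7 (0.128, 0.0959 to 0.169). These genes were not spread over the class alike, since wnt2bb stood among the leading genes of a sub-cluster of 120 light damage and 13 NMDA cells and cadpsb among those of 1 of 70 and 19 cells. At the finer resolution cadpsb and hspg2 were both among those of a sub-cluster of 17.9% and 2.79% of cone-like cells. Photoreceptor transcription factor genes had a median of 0.90 (16 genes), which was 0.17 in cluster 12 alone. With predicted doublets kept, the log2 ratio was 1.45 for opn1mw1, 2.47 for prdm1a and -4.37 for hspg2, and thinned to 1000 UMIs per cell it was 2.62 for opn1mw1 and 6.68 for prdm1a. Rod phototransduction genes had a median of 1.52 (18 genes), and rho, the rod opsin gene, stood at 52.3 and 253 CPM. Rod RNA, free or in doublets, was not tested as a source in cone-like cells.

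In horizontal-like cells rnf213b, a ubiquitin ligase gene, had 0.942 and 100.5 CPM (4 and 411 UMIs) and ifi45 had 33.4 and 1024, a ratio of 30.6 (25.9 to 36.5). Higher after light damage there were mst1, at 79.8 and 0.489 CPM (339 and 2 UMIs), the calcium pump gene atp2b3b, at 209 and 24.0 (0.115, 0.0921 to 0.141), and the inositol kinase gene itpkcb, at 52.5 and 7.09 (0.135, 0.0884 to 0.199). The largest cluster of the bipolar-like class was cluster 21 after light damage and cluster 10 after NMDA. In bipolar-like cells dhx58, which encodes a cytosolic RNA sensor, had 1 UMI after light damage and 159 after NMDA, and the ephrin gene efna5a had 3 and 158. The chloride transporter gene clcn5b, at 50.8 and 3.82 CPM, the aldehyde dehydrogenase gene aldh2.2, at 113 and 21.4, and pdlim1, at 70.24 and 13.4, were higher after light damage. Signalling genes of ON bipolar cells had a median of -0.47 (12 genes, percentile 1.21), and OFF bipolar genes one of 0.66 (8 genes, percentile 97.4) with cabp2a at -1.55. The median gene of all lay at 0.11 in bipolar-like cells. With predicted doublets kept, the log2 ratio was 4.77 for isg15, 3.45 for dhx58 and -2.46 for clcn5b in bipolar-like cells and 5.54 for isg15, 4.47 for rnf213b and 4.13 for ifi45 in horizontal-like cells.

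Of the amacrine-like cells, cluster 13 held 635 of the 896 NMDA cells, while light damage cells were spread over clusters 13, 28 and 30 with 76, 78 and 76 cells. Cholinergic and dopaminergic genes had a median of -1.02 (10 genes, percentile 0), with chata, the acetylcholine-synthesizing enzyme gene, at 1136 and 480 CPM and the vesicular transporter gene slc18a3a at 323 and 134. The gene chata was among the 10 leading genes of clusters 28 and 30. These held 33.9% and 33.0% of amacrine-like cells after light damage and 14.8% and 14.3% after NMDA. The mix of clusters therefore cannot be told apart from lower expression, and levels within clusters 28 and 30 were not compared. Genes of GABA and glycine transmission had a median of -0.15 at percentile 37.3. The galectin gene lgals17 had no UMI after light damage and 115 CPM after NMDA, with a lower bound of 59.7 for the ratio, and the bound for stat1b was 55.1. With predicted doublets kept their log2 ratios, 6.86 and 6.75 before, were 4.87 and 5.995. Neuropeptide genes had a median of 0.43 (9 genes, percentile 98.9), which was -0.24 with predicted doublets kept and -0.20 within the largest cluster alone, and single members rested on few cells. Of the 4380 UMIs of ccka, the cholecystokinin gene, after NMDA, 93.3% lay in 10 cells. After light damage npb was found in 6 cells, adcyap1a, the PACAP gene, in 5 and npy in 2.

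Ganglion-like cells were all of cluster 11, and their 200 cells after light damage lay at the minimum set for a class. The proneural gene atoh7, which ganglion cells need to form, had 1 UMI after light damage and 846 after NMDA, the latter in 40 of 539 cells. The chemokine receptor gene cxcr4b had 1 and 635 UMIs, the latter in 39 cells, and dhx58 stood at 1.17 and 69.7 CPM. Higher after light damage were stc2a, at 202 and 20.3 CPM, tcap, at 80.8 and 15.3, and the chaperone gene hspa8b, at 64.2 and 13.2. Of their light damage UMIs 10 cells held 92.8%, 89.2% and 55.9%, and 1 cell held 36.5% of those of stc2a. With predicted doublets kept the log2 ratio was 5.25 for cxcr4b, 4.08 for dhx58 and -2.54 for stc2a. Ganglion cell transcription factor genes had a median of 0.13 (18 genes, percentile 87.1), with satb1b at 0.89 and tbx20 at -1.41. Under another scaling of the sums (TMM) the whole class shifted by -0.01, and the largest such shifts were 0.12 in horizontal-like and bipolar-like cells and 0.10 in cone-like cells.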

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

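A small cluster outside the classes compared held genes of microglia and of myelin-forming cells. It was led by the microglia genes apoc1, ccl34b.1 and cd74a beside the myelin genes mbpb and plp1b, and took 0.173% of the light damage cells and 0.363% of the NMDA cells, above the 0.0236% and 0.0173% that a count of 0 allows. The intervals were 0.108 to 0.262% (22 cells) and 0.279 to 0.464% (63 cells). The eGFP sort would remove such cells if they carried no reporter. No explanation was tested for their presence.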

How the results depend on the processing

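The alternatives that named every cluster by its best class, took the largest cluster of a class or kept cells from 200 genes were chosen after the data were seen. Of the recomputed log2 ratios of class shares, 58 stayed within the counting interval, 20 moved and 2 turned. With each library clustered alone, the ratio was 0.13 for Müller glia-like and 0.0196 for cycling cells, so both turned, and it was 2.44 for amacrine-, 1.07 for bipolar-, 1.02 for horizontal- and -1.45 for rod-like cells. The rod-like value came from shares of 19.2% and 7.01%, where the naming of clusters may differ between the libraries. The class given per cell gave 1.05 for amacrine-, 0.23 for bipolar-, 0.20 for ganglion-, 0.45 for horizontal- and -0.75 for Müller glia-like cells. From 1000 genes the ratio was 1.78 for amacrine-, 0.54 for horizontal- and -0.20 for Müller glia-like cells, and from 200 genes it was -0.43 for the latter. Leiden resolution 0.5 gave 1.88 for amacrine- and 0.62 for horizontal-like cells, resolution 2 gave 0.62 and kept doublets 0.61 for the latter. Cone-like cells had -0.39 at the 10% mitochondrial limit and -0.28 with no limit, and Müller glia-like cells -0.22 with every cluster named.

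Of the recomputed opsin shares 38 stayed within their interval and 10 moved. From 10 opsin UMIs with 80% of 1 group, UV was 18.1% after NMDA, blue 0.658% after light damage and 1.45% after NMDA, green 8.55% after light damage and 16.7% after NMDA, against 17.4% and 12.8% by the most abundant group, and red 87.5% and 63.8%. At the 10% mitochondrial limit UV was 22.8% and red 58.4% after NMDA and green 22.0% after light damage, and with no limit red was 72.9% after light damage.

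A list median stayed when it lay within an interval set by the spread between the list's members, and not by counting error. This interval was wide, such as 1.87 to 6.64 for interferon genes in amacrine-like cells. Of the interferon and immediate early medians 139 stayed and 4 moved. With members counted from 1 UMI, an interferon median that fell from 4.18 to 2.38 in amacrine-like cells still counted as stayed. So did falls from 3.35 to 1.95 in horizontal-like and from 3.06 to 1.78 in cone-like cells. In the largest cluster alone the interferon median of Müller glia-like cells was 0.71, and the immediate early medians of cycling and horizontal-like cells were -0.80 and -0.47. With no mitochondrial limit the cycling median was -0.68. Of the other list medians 1407 stayed, 77 moved and 12 turned. Nuclear oxidative phosphorylation genes turned to 0.0271 in rod-like cells under TMM and 0.0313 from 1000 genes, and to 0.0164 in the largest bipolar-like cluster. Mitochondrially encoded genes turned to 0.13 in rod-like cells at the 10% limit, and in amacrine-like cells to -0.0249 with doublets kept and -0.14 with no limit. GABA and glycine genes in horizontal-like cells turned to 0.15 with doublets kept and 0.0585 with members from 1 UMI, where cell cycle genes turned to 0.32. Rod phototransduction genes in amacrine-like cells turned to 1.05 as means per cell and 0.22 from 1 UMI, and oxidative stress genes to -0.11 in the largest cone-like cluster. The cause was not tested. Of the ratios of genes named singly 218 stayed, 70 moved and none turned, and of the sub-cluster shares 14 stayed and 16 moved at resolution 1. Depth limits the ratios of genes with few UMIs, such as dhx58 with 1 UMI in the light damage bipolar-like cells. No paired analysis was possible because each injury had 1 library.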

Other observations

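The tests chosen only after the results were seen were those of the animals or handling of a library, of the lower share of Müller glia-like cells, of the minimum of detected genes, of dissociation, and both that used the glial cluster with the highest interferon level. The test of detected genes took the place of a stricter minimum of 1000 genes set beforehand, which gave an amacrine-like ratio of 3.44 but removes still more shallow cells and so decided nothing.

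Some fixed lists not described so far also set the libraries apart. The death receptor gene fas had the highest or second highest ratio of the p53 and apoptosis list in most classes, at 25.3 and 100.5 CPM in Müller glia-like, 5.22 and 43.5 in amacrine-like and 8.85 and 52.0 in bipolar-like cells. The list as a whole had medians of 0.17 in Müller glia-like, -0.65 in rod-like and -0.53 in ganglion-like cells. The chemokine gene cxcl18b stood at 173 and 981 CPM in Müller glia-like cells. Presynaptic genes had a median of 0.55 in Müller glia-like cells (11 genes), with syn2b the highest. The naming rule had kept glial clusters rich in these genes out of the class. Neuronal RNA, free or in doublets, was not tested as a source, and amacrine-, ganglion- and bipolar-like shares were larger after NMDA. Circadian genes lay near 0 in Müller glia-like (-0.07), rod-like (0.01) and ganglion-like cells (0.03), and at -0.40 in bipolar-like cells.

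For the interferon difference, RNA from microglia or macrophages was tested in Müller glia-like cells, where the largest microglia share that the markers allow could give 3.15% of the difference, and apoc1 stood at 34.1 and 32.5 CPM in those cells against 8682 in the microglia-containing cluster. Free RNA or doublets with glia were tested by the ratio of the interferon level to the glial marker level in horizontal-, bipolar-, amacrine- and ganglion-like cells, and not in rod- and cone-like cells. These tests left out the list's cd74a, cd74b and mhc2a. Against the mean glial level the lowest ratio was 2.95, past the bound of 2 set beforehand. That bound was wrong, because the mean understates a source rich in interferon RNA. Against the richest glial cluster, horizontal-like cells had 17.6, which argues against RNA from that cluster there. Bipolar- and ganglion-like cells had 4.98 and 3.86, also past 2. That cluster's level is a mean too, and a glial sub-cluster led by interferon genes (54 light damage and 1211 NMDA cells) was not used. Against it the ratios could be lower, so glial RNA stays open in bipolar- and ganglion-like cells. In amacrine-like cells the ratio against the richest cluster was 1.45, so glial RNA cannot be told apart from their own expression. With 1 library per injury, an infection or other state of the animals, or their handling, also stays open beside the injury itself.

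The larger share of amacrine-like cells after NMDA was weighed next. A lower share of Müller glia-like cells would raise all other classes alike, but among the other cells the amacrine ratio was 2.52 (2.18 to 2.92) and the rod ratio 0.727 (0.670 to 0.789). The minimum of 500 detected genes could have removed shallow amacrine-like cells of the light damage library. Yet with a minimum of 200, which added 1585 light damage and 1700 NMDA barcodes, the ratio was 2.75 (2.39 to 3.17). It was 2.84 (2.55 to 3.17) when clusters with at least 3 enriched markers took their best class. Under that naming 137 and 212 of the added barcodes stayed unnamed. Of the added barcodes, 938 and 1211 lay in unnamed clusters under the first naming, and barcodes under 200 genes were not tested. The kind of injury, and differences in sorting, dissociation or animals between these libraries, were not tested and stay open.

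Immediate early genes, lower after NMDA, came last. Another mix of clusters in the rod-like class was argued against by the largest rod-like cluster alone, where the median was -1.19. A different mix of sub-clusters was not tested and stays open. At the finer resolution a rod-like sub-cluster with junbb, ier2b and atf3 held 268 light damage and 173 NMDA cells, and another with atf3 213 and 161. At the coarser one, a sub-cluster with junbb held 289 and 257 and one with atf3 436 and 510. A dissociation or handling that differed between the libraries would lower the list in each class, and 7 of the 8 classes had a median below 0. The horizontal-like median of 0.09 lay within the range of random lists, while in the largest clusters alone it was -0.47 in horizontal-like and 0.0723 in cone-like cells, so handling cannot be told apart from a difference in the state of the cells. The kind of injury stays open too, as untested.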
